A study of Mus musculus with 9 samples.

How the data were processed

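Total lung RNA from 9 mice was measured by RNA sequencing, with 1 library per mouse and 3 mice in each of 3 groups: control mice given vehicle, TGFα mice given vehicle, and TGFα mice given pirfenidone. Per the labels, total RNA was extracted with a column kit, libraries followed standard Illumina protocols, and the TGFα mice received doxycycline (Dox) for 6 weeks. Per the series description, vehicle or pirfenidone was given in the last 3 weeks. The submitters' processing notes name bcl2fastq, CASAVA 1.8, TopHat and DESeq and the mouse genome build mm10 (GRCm38), without the role of each tool. The annotation, the counting method and the filter on genes are not given in the sources used here.

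The deposited table holds RPKM values (reads per kilobase of gene length, scaled to the reads of the library) made by the authors for 16165 genes, and all 9 of its columns used here belong to the 9 libraries. Its header names no unit. The unit was settled from the values. After division by 1 step per gene and library, 100% of the values were whole numbers of reads. The tolerance was 0.0001 reads, and a looser one for 2 genes that were settled by trying whole gene lengths. The steps of different genes stood in ratios of whole gene lengths. The read recovery was tested on simulated data, where all reads of 1912 of 1917 genes (99.7%) came back exactly. The library totals behind the values ranged from 11428709 to 18874158 reads. A floor of 3 reads in a gene equalled 0.159 to 0.263 RPM (the same scaling without gene length), and this floor covers counting error only. Symbols of 29 genes that the table lacked or held as dates were taken from RefSeq by gene identifier. Gene positions are those of RefSeq on GRCm38.

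Genes with more than 1 RPKM in at least 3 libraries were tested, 13849 in all. Values were analysed as log2(RPKM + 1) with limma-trend (limma 3.58.1 in R 4.3.3), in 1 model with group as the only term over all 9 libraries, which left 6 residual degrees of freedom and a prior of 2.67. The tests were two-sided, and p values were adjusted by Benjamini-Hochberg across the tested genes within each comparison, with a threshold of 0.05. With log2(RPKM + 1), fold changes of genes with few RPKM are understated, so folds in the text are ratios of mean RPKM and log2 fold changes are those of the model. Of 47 gene lists with 1039 entries, the 44 with at least 5 measured members were tested with limma's camera at a preset inter-gene correlation of 0.01, with adjustment across the lists. The same lists were tested with the correlation estimated from the data and with fry. Within each list, genes were also adjusted over the list alone. Each count of changed genes stands beside the other splits of the same libraries. Of genes changed between TGFα vehicle and control, the share that pirfenidone moved the opposite way was taken. This share, the median return of these genes and the number that passed both ways were set beside 100 simulated data sets. These data sets had no drug effect and kept the correlation between genes. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 was used for the read recovery and the figures.

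The groups, the 3 comparisons, the tests, the gene lists and the rule for named genes were chosen before the data were examined. The first choice was a test on raw counts, and the test used here was the one set for a table without raw counts. By the rule, the text names Tgfa, Col1a1, Col3a1, Fn1, Acta2 and Wt1 in every comparison. For both comparisons that involve TGFα mice on vehicle, it takes the 6 largest increases and 6 largest decreases among genes that passed the threshold, had an average log2 CPM of at least 1 and had replicates that did not overlap between the groups. Predicted and clone-named genes were left out. It also takes the 2 members with the smallest p of each pathway list and of each cell-type list called by camera, and 1 of each pathway list that was not called. For pirfenidone against control, it takes the 3 largest changes each way. Not every gene of the rule is described, some genes are not reported here, and genes outside it are marked in the text or stand as members of a counted list.

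The analysis was tested on simulated data with changes of known size. Of genes changed 2-fold, 88.1%, 85.1% and 94.0% were called with the right direction in the comparisons of TGFα vehicle with control, pirfenidone with TGFα vehicle, and pirfenidone with control, among 13807, 13812 and 13802 genes tested. Of genes changed 1.5-fold, 50.7%, 59.7% and 59.7% were called, and of genes changed 4-fold 97.0%, 98.5% and 98.5%. Unchanged genes made up 2.58%, 5.85% and 5.16% of the calls. Both shifted lists were called in each comparison, and 0 of 43 others. The simulated genes varied independently of each other, so this does not test false list calls among correlated genes. All simulated libraries varied alike, and the changed genes had an average log2 CPM of at least 1. Some real libraries stood apart from their groups, so the shares of genes called and of false calls may differ in the real data. The opposite share was 48.7% without a drug effect and 100% with a full return to control.

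Alternatives covered other scalings of the libraries, other filters and pseudocounts, limma-voom on the recovered reads, a fit of only the 2 groups compared, a block for the replicate number, stricter thresholds, and leaving out each library in turn. After the data were seen, a correction for GC content and transcript length was added (natural splines with 4 degrees of freedom on the longest GENCODE transcript, available for 96.86% of the tested genes), as were a fit without 2 libraries that stood apart from their groups, fits with sample weights, and the simulated values of the median return and of genes that passed both ways.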

Results

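Gene expression was measured in the lungs of 9 mice, 3 in each of 3 groups, with 1 library of total lung RNA per mouse. TGFα mice carry a transgene for transforming growth factor alpha, a ligand of the EGF receptor, and serve as a model of lung fibrosis. They received Dox for 6 weeks and either vehicle or pirfenidone, an antifibrotic drug, for the last 3 weeks. The labels of the control mice, which received vehicle, name no Dox, and no control mice received pirfenidone. Differences between TGFα and control lungs can therefore not be assigned to the transgene rather than to Dox. Wording such as "with the transgene" or "by the transgene" stands below for both together. Control libraries held 16815301, 15474002 and 16923531 reads. Libraries of TGFα mice held 18634015, 16327952 and 18874158 reads with vehicle and 11428709, 13219916 and 14125367 with pirfenidone. Values are the deposited RPKM, given as mean ± SD of 3 mice, folds are ratios of mean RPKM, and adjusted p values of genes are from limma across 13849 genes. The first principal component, with 44.1% of the variance, placed the 3 control libraries between -39.9 and -32.4 and the 6 TGFα libraries between 11.5 and 25.4. On the second, with 25.4%, vehicle libraries 2 and 3 lay at -26.9 and -27.1 and pirfenidone libraries 1 and 2 at 28.3 and 33.6. Vehicle library 1 lay at 3.73 and pirfenidone library 3 at -16.4, each nearer to the other group than its companions were.

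**Figure D1:**
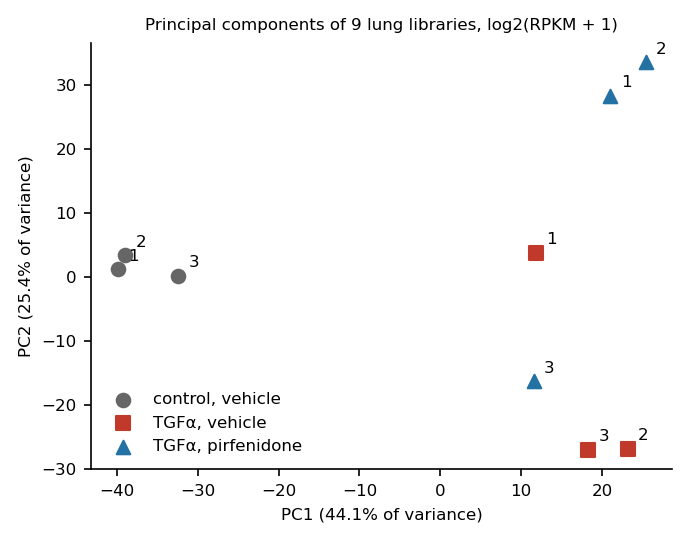
Each point is 1 library, placed by its first principal component (44.1% of the variance, x axis) and its second (25.4%, y axis), and coloured by group. The control libraries lie between -39.9 and -32.4 on the x axis, and pirfenidone library 3 lies at -16.4 on the y axis, apart from the other pirfenidone libraries.

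TGFα mice on vehicle were compared with control mice to ask which lung transcripts differ with the transgene. Matrix genes were among the largest increases. Lum (lumican, a proteoglycan that binds collagen fibrils) rose 12.5-fold, from 6.67 ± 1.38 to 83.4 ± 14.3 RPKM (n = 3, log2 fold change 3.46, SE 0.36, adjusted p = 0.00135). Tnc (tenascin C) rose from 4.14 ± 1.18 to 48.1 ± 18.9 RPKM and Col15a1 (a basement membrane collagen) from 5.78 ± 0.879 to 60.7 ± 9.65 RPKM. Fn1 (fibronectin, gene 14268, GRCm38 chromosome 1, 71585473 to 71653280) rose 4.03-fold, from 68.0 ± 7.24 to 274 ± 54.1 RPKM (log2 fold change 1.98, SE 0.24, adjusted p = 0.00183). Col1a1 (type I collagen, gene 12842, chromosome 11, 94936224 to 94953042) rose 2.12-fold, from 88.1 ± 4.89 to 187 ± 44.6 RPKM (log2 fold change 1.05, SE 0.21, adjusted p = 0.00995). Col3a1 (type III collagen, gene 12825, chromosome 1, 45311538 to 45349706) rose 1.95-fold, from 245 ± 23.4 to 478 ± 94.4 RPKM (log2 fold change 0.95, SE 0.23, adjusted p = 0.0214). The call of Col3a1 was lost without control library 1 (adjusted p = 0.0753), control library 2 (0.0588), vehicle library 2 (0.0702) or vehicle library 3 (0.0856). Tgfa itself (gene 21802, chromosome 6, 86195038 to 86275744) stood at 6.84 ± 0.789 RPKM in control and 6.85 ± 0.825 RPKM in TGFα lungs (log2 fold change 0.00, SE 0.11, adjusted p = 0.989), and its sign differed between scalings of the libraries. The sources used here do not give the transgene's sequence, so whether its reads count towards mouse Tgfa is not known, and these values do not measure the transgene. The largest increase under the rule was Mycn (a MYC-family transcription factor, gene 18109, chromosome 12, 12936093 to 12941836), from 1.31 ± 0.599 to 105 ± 44.8 RPKM (log2 fold change 5.44, SE 0.76, adjusted p = 0.003). Ptn (pleiotrophin, a heparin-binding growth factor) rose from 0.462 ± 0.0305 to 32.0 ± 6.55 RPKM and Angptl7 (an angiopoietin-like protein) from 0.262 ± 0.127 to 15.8 ± 5.65 RPKM.

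Of 34 measured matrix glycoproteins, 12 rose, 4 fell and 18 did not pass, and 17 rose and 4 fell when adjusted over the list alone. The list had a median log2 fold change of 0.66 (camera adjusted p = 0.00324, adjusted p = 0.595 with an estimated correlation). Vcan (versican) rose from 1.53 ± 0.373 to 21.1 ± 6.23 RPKM and Thbs2 (thrombospondin 2) from 0.419 ± 0.104 to 10.7 ± 2.24 RPKM, while Tnxb, Vtn, Ogn and Postn fell. Among 18 fibrillar and associated collagens, 7 rose and 2, Col27a1 and Col6a3, fell, with 8 and 2 when adjusted over the list alone (camera adjusted p = 0.0444, adjusted p = 0.686 with an estimated correlation). Col8a1 rose from 4.09 ± 1.07 to 33.8 ± 7.17 RPKM and Col16a1 from 9.14 ± 1.09 to 24.1 ± 5.01 RPKM. The collagen list was not called without control library 3 (adjusted p = 0.191), vehicle library 1 (0.062) or vehicle library 3 (0.055). Cross-linking enzymes, matrix proteases and their inhibitors had 10 members that rose and 2, Mmp9 and Loxl4, that fell among 34, with 12 and 2 when adjusted over the list alone (camera adjusted p = 0.043, adjusted p = 0.661 with an estimated correlation). Lox, Loxl1, Loxl2 and Loxl3, which cross-link collagen and elastin, all rose, and Adamts12 rose from 0.494 ± 0.102 to 3.90 ± 0.944 RPKM. Mmp9 fell from 7.94 ± 1.81 to 2.37 ± 0.282 RPKM, and the list was not called without vehicle library 1 (adjusted p = 0.058). In the TGF-beta list, 5 of 22 members rose (Tgfb3, Pmepa1, Ltbp2, Tgfbr1 and Tgfbi) and 0 fell, also when adjusted over the list alone (camera adjusted p = 0.0258, adjusted p = 0.464 with an estimated correlation). Tgfb3, a TGF-beta ligand, rose from 14.5 ± 1.52 to 33.6 ± 3.25 RPKM and Pmepa1, a TGF-beta target, from 17.5 ± 2.25 to 41.7 ± 6.92 RPKM. Skeletal muscle transcripts were present in some TGFα libraries: Acta1 (skeletal actin) stood at 407, 158 and 0.540 RPKM in vehicle libraries 1, 2 and 3 and at 0.451 to 0.740 RPKM in control libraries. None of 12 skeletal muscle markers passed limma's threshold over all genes or when adjusted over the list alone. Their median log2 fold change was 2.97 (camera adjusted p = 0.0396, adjusted p = 0.687 with an estimated correlation), and the call was lost without control library 3 (0.079), vehicle library 1 (0.321) or vehicle library 2 (0.054).

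Acta2 (smooth muscle actin, gene 11475, chromosome 19, 34240336 to 34255585) fell from 78.7 ± 13.8 to 29.4 ± 3.20 RPKM (log2 fold change -1.38, SE 0.19, adjusted p = 0.0028). Cnn1 (calponin) fell from 15.3 ± 3.01 to 6.09 ± 0.464 RPKM and Myh11 (smooth muscle myosin) from 29.0 ± 5.43 to 10.8 ± 3.28 RPKM. In the contractile list 7 of 20 members fell and 1, Itgav, rose, with 8 and 1 when adjusted over the list alone (camera adjusted p = 0.0152, adjusted p = 0.644 with an estimated correlation). Smooth muscle and pericyte markers had 8 that fell and 1 that rose among 19, with 8 and 2 when adjusted over the list alone (camera adjusted p = 0.0191, adjusted p = 0.661 with an estimated correlation). The one that rose was Rgs5, a pericyte marker, from 3.09 ± 0.426 to 22.3 ± 5.43 RPKM. Fibroblast markers had 6 of 25 members that rose and 5, Clec3b, Dpt, Fgfr4, Limch1 and Gpc3, that fell, with 7 and 8 when adjusted over the list alone, and the list was not called (camera adjusted p = 0.594), with a median of -0.15, a mean of 0.01 and a camera direction of lower. Dpt (dermatopontin) fell from 114 ± 9.28 to 17.6 ± 17.3 RPKM and Wisp2 from 45.2 ± 11.1 to 8.21 ± 1.16 RPKM. Regulators of activated fibroblasts had 5 of 30 members that rose, Twist1, Sox9, Runx1, Wt1 and Gli1, and 7 that fell, with 8 and 9 when adjusted over the list alone (camera adjusted p = 0.834, direction lower, median 0.07 and mean 0.08). Twist1, a mesenchymal transcription factor, rose from 0.0617 ± 0.0191 to 5.77 ± 1.32 RPKM. Wt1 (Wilms tumour 1, found in mesothelium and in activated lung fibroblasts, gene 22431, chromosome 2, 105126529 to 105173614) rose 2.75-fold, from 2.63 ± 1.14 to 7.24 ± 1.37 RPKM (log2 fold change 1.21, SE 0.32, adjusted p = 0.0271). The Wt1 call was lost without control library 2 (adjusted p = 0.0927), control library 3 (0.0613), vehicle library 1 (0.0606), vehicle library 2 (0.0571) or vehicle library 3 (0.0878). Mesothelial markers had 4 of 10 members that fell, Gpm6a, Upk3b, Rspo1 and Lrrn4, and 1, Wt1, that rose, with 6 and 2 when adjusted over the list alone (camera adjusted p = 0.0225, adjusted p = 0.485 with an estimated correlation). Without vehicle library 1 the mesothelial list was not called (adjusted p = 0.053). Cardiac muscle markers, which mouse lung holds in the walls of its large veins, had 9 of 15 members that fell, also when adjusted over the list alone (camera adjusted p = 7.81e-06, adjusted p = 0.464 with an estimated correlation). Actc1, Tnnt2 and Myl7, genes of the cardiac sarcomere, fell 5.74-fold, 5.67-fold and 5.62-fold. Myh6 (a cardiac myosin, chosen after its values were seen) stood at 32.5, 70.5 and 36.7 RPKM in control and 11.6, 7.52 and 8.48 RPKM in vehicle libraries.

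Endothelial transcripts were lower in TGFα lungs. Of 25 endothelial markers, 21 fell and 0 rose, with 22 when adjusted over the list alone and a median of -1.04 (camera adjusted p = 6.21e-13, adjusted p = 0.432 with an estimated correlation). Eng (endoglin) fell 3.87-fold, from 151 ± 40.1 to 39.1 ± 5.01 RPKM, and Cldn5 (a tight junction protein of endothelium) from 408 ± 61.4 to 127 ± 27.3 RPKM. Bmp6, a bone morphogenetic protein, fell from 78.6 ± 19.5 to 14.1 ± 5.42 RPKM. Ciliated cell markers had 14 of 19 members that fell, with 17 when adjusted over the list alone (camera adjusted p = 4.78e-09, adjusted p = 0.464 with an estimated correlation). Tppp3 fell from 265 ± 45.7 to 95.8 ± 21.3 RPKM. In the alveolar epithelium, 6 of 15 markers of alveolar type 1 cells fell, with 8 when adjusted over the list alone (camera adjusted p = 9.98e-05, adjusted p = 0.531 with an estimated correlation). Igfbp2 fell from 165 ± 38.1 to 40.4 ± 6.43 RPKM and Pdpn (podoplanin) from 67.4 ± 1.33 to 37.8 ± 2.57 RPKM. Alveolar type 2 markers had 6 of 15 members that rose and 2, Lyz1 and Cxcl15, that fell, with 7 and 2 when adjusted over the list alone (camera adjusted p = 0.0176, adjusted p = 0.575 with an estimated correlation). Napsa (napsin A, which processes surfactant protein B) rose from 164 ± 7.45 to 294 ± 21.7 RPKM and Etv5 from 40.2 ± 3.23 to 64.0 ± 4.81 RPKM.

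Lists of T, B and natural killer cell, granulocyte and blood cell markers were lower as well. Plasma cell markers were not called, with 2 of 12 that rose and 1 that fell (camera adjusted p = 0.596). T cell markers had 16 of 19 members that fell, with 17 when adjusted over the list alone (camera adjusted p = 1.05e-10, adjusted p = 0.432 with an estimated correlation). Tcf7 fell from 21.3 ± 2.35 to 11.2 ± 1.22 RPKM. B cell markers had 11 of 15 that fell, with 13 when adjusted over the list alone (camera adjusted p = 8.84e-09, adjusted p = 0.432 with an estimated correlation). Cxcr5, a chemokine receptor, fell from 5.43 ± 0.336 to 2.11 ± 0.453 RPKM. All 11 natural killer cell markers fell, also when adjusted over the list alone (camera adjusted p = 2.62e-07, adjusted p = 0.432 with an estimated correlation). Nkg7, a protein of cytotoxic granules, fell from 12.6 ± 1.46 to 4.95 ± 0.800 RPKM. Neutrophil markers had 5 of 11 that fell, Mmp9, Csf3r, Cxcr2, S100a8 and S100a9, with 7 when adjusted over the list alone (camera adjusted p = 0.000944, adjusted p = 0.432 with an estimated correlation). Among mast cell, basophil and eosinophil markers 4 of 11 fell, Kit, Hdc, Gata2 and Alox15, also when adjusted over the list alone (camera adjusted p = 0.0294, adjusted p = 0.432 with an estimated correlation). With median-of-ratios scaling the mast cell list was not called (adjusted p = 0.051). Platelet markers had 7 of 8 members that fell, also when adjusted over the list alone (camera adjusted p = 0.000871, adjusted p = 0.432 with an estimated correlation). Ppbp fell from 16.8 ± 2.02 to 5.09 ± 1.99 RPKM. Erythroid markers had 5 of 6 that fell, among them Slc4a1, Alas2 and Bpgm, with 5 that fell and 1 that rose when adjusted over the list alone (camera adjusted p = 0.0011, adjusted p = 0.432 with an estimated correlation). Slc4a1 (the anion exchanger of red cells) fell from 2.84 ± 0.998 to 0.277 ± 0.0466 RPKM. Interferon-induced genes had 6 of 28 that fell, with 7 when adjusted over the list alone (camera adjusted p = 0.000335, adjusted p = 0.531 with an estimated correlation). Ddx58, a sensor of viral RNA, fell from 17.8 ± 0.427 to 13.1 ± 0.788 RPKM. Inflammatory cytokines and chemokines were not called, with 2 that rose, Nos2 and Il18, and 5 that fell, Ccl5, S100a8, S100a9, Csf1 and Cxcl15, among 26. Ccl5, a chemokine of T and natural killer cells, fell 3.30-fold, from 46.5 ± 1.25 to 14.1 ± 2.97 RPKM (log2 fold change -1.67, SE 0.14, adjusted p = 0.000736).

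Of 26 EGF receptor ligands and ERK feedback genes, 10 rose and 3, Hbegf, Ccnd1 and Epha2, fell, with 11 and 3 when adjusted over the list alone (camera adjusted p = 0.017, adjusted p = 0.531 with an estimated correlation). Etv4, an ERK-induced transcription factor, rose from 0.254 ± 0.0666 to 7.61 ± 1.57 RPKM, and Ereg (epiregulin, an EGF receptor ligand) from 0.0773 ± 0.109 to 1.56 ± 0.325 RPKM. The EGF receptor list was not called without control library 3 (adjusted p = 0.099). Immediate early genes had 10 of 20 that fell and 2, Egr1 and Egr3, that rose, also when adjusted over the list alone (camera adjusted p = 0.000576, adjusted p = 0.464 with an estimated correlation). Klf4 fell from 107 ± 29.4 to 32.1 ± 8.39 RPKM. Ribosomal protein genes had 47 of 48 members that rose, also when adjusted over the list alone, with a median of 0.79 (camera adjusted p = 5.68e-19, adjusted p = 0.464 with an estimated correlation). Respiratory chain subunits had 8 of 35 that rose (4 with median-of-ratios scaling), also when adjusted over the list alone (camera adjusted p = 0.000944, adjusted p = 0.661 with an estimated correlation). Xenobiotic and antioxidant genes had 7 of 30 that fell, with 7 that fell and 1 that rose when adjusted over the list alone (camera adjusted p = 0.000909, adjusted p = 0.531 with an estimated correlation). Fmo1, a flavin monooxygenase, fell from 207 ± 63.6 to 46.0 ± 14.8 RPKM. In the cell cycle list 1 of 43 genes, Rrm1 (a ribonucleotide reductase subunit), rose, from 9.81 ± 1.27 to 15 ± 2.14 RPKM, and 0 when adjusted over the list alone by limma (camera adjusted p = 0.017, adjusted p = 0.768 with an estimated correlation). Without control library 1 (adjusted p = 0.099), control library 2 (0.095), vehicle library 2 (0.109) or vehicle library 3 (0.071) the cell cycle list was not called.

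In all, 3222 of 13849 genes changed between TGFα mice on vehicle and control mice, 1665 higher and 1557 lower, of which 303 and 367 changed at least 2-fold. Lower genes were the majority with median-of-ratios scaling (1445 higher, 1778 lower) and after the correction for GC content and transcript length (1456 higher, 1707 lower). Replicates did not overlap for 44.2% of genes, against 10% by chance for 3 mice against 3. Camera called 27 of 44 lists, 10 higher and 17 lower, and 0 with an estimated correlation. Mixed splits of the same libraries gave 17 to 27 called lists. The median log2 fold change of all genes was 0.04. The count was 1667 without control library 1, 1614 without control library 2, 1361 without vehicle library 2 and 1317 without vehicle library 3. Rrm1, Irf1, Cox7b, Ndufb5, Gucy1b3, Gata3, Ddit3 and Gp9, which passed with all libraries, each lost the call without at least 1 of these or the other libraries (adjusted p from 0.0514 to 0.108).

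**Figure D2:**
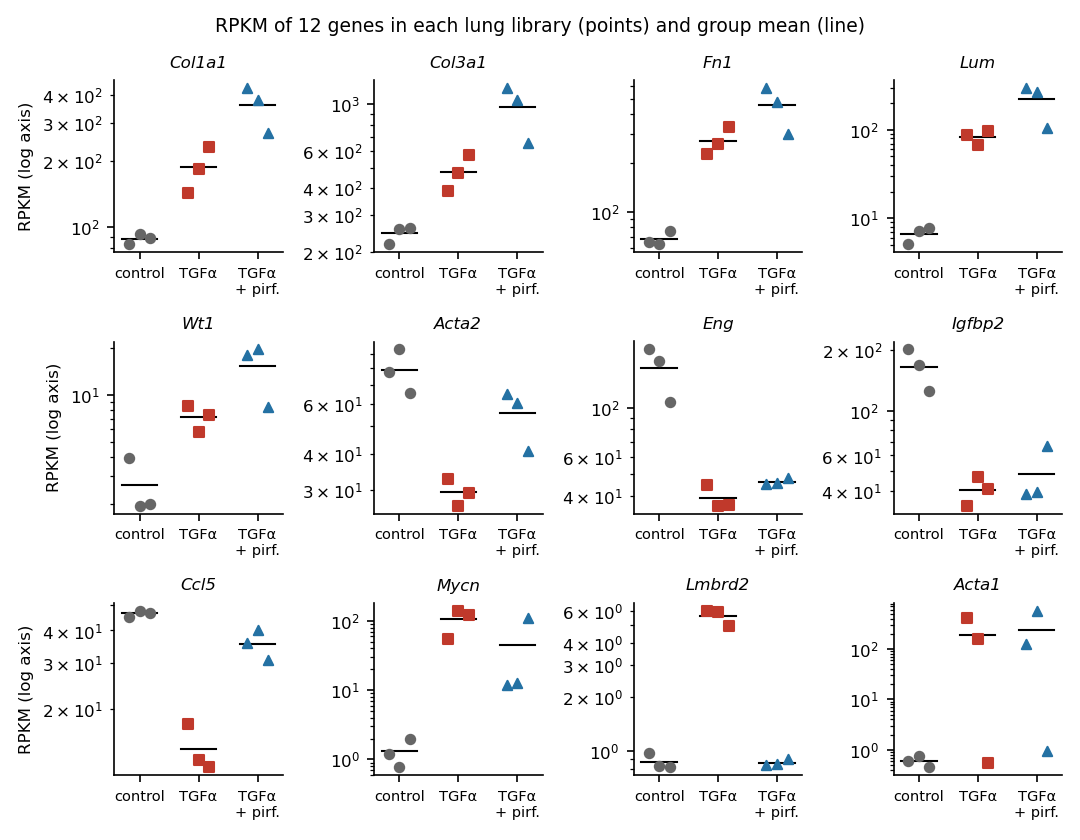
RPKM of 12 genes (y axis, logarithmic) in the 3 groups (x axis), with 1 point per library and a line at each mean (n = 3). Lum stands at 6.67, 83.4 and 223 RPKM in control, TGFα vehicle and TGFα pirfenidone lungs, and Lmbrd2 at 0.873, 5.64 and 0.861 RPKM.

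TGFα mice on pirfenidone were compared with TGFα mice on vehicle to ask which transcripts of the transgenic lung differ with the drug. The firmest differences were genes that were low in control lungs, higher with the transgene, and near the control level with pirfenidone. Lmbrd2 (gene 320506, chromosome 15, 9140528 to 9202483) stood at 0.873 ± 0.0898 RPKM in control, 5.64 ± 0.581 RPKM in vehicle and 0.861 ± 0.0395 RPKM in pirfenidone lungs (n = 3, log2 fold change -1.83, SE 0.10, adjusted p = 0.000629). Zbed6, a transcription factor derived from a transposon, fell from 16.2 ± 0.146 to 3.91 ± 0.658 RPKM, with 3.93 ± 0.603 RPKM in control lungs (log2 fold change -1.82, SE 0.12, adjusted p = 0.00109). Mib1, a ubiquitin ligase of Notch signalling, fell from 12.5 ± 0.491 to 4.25 ± 0.815 RPKM, and Klhl11 from 4.87 ± 0.275 to 1.14 ± 0.247 RPKM (adjusted p = 0.00318 for each). Gprin3 fell from 3.88 ± 1.06 to 0.565 ± 0.0285 RPKM, and Atp6v0a4, a subunit of the proton pump, from 8.57 ± 2.55 to 1.62 ± 1.11 RPKM. Among the increases, Ccl5 (gene 20304) rose 2.53-fold, from 14.1 ± 2.97 to 35.6 ± 4.63 RPKM (log2 fold change 1.29, SE 0.14, adjusted p = 0.00818), beside 46.5 ± 1.25 RPKM in control lungs. Lst1, a leukocyte gene, rose from 12.7 ± 1.07 to 30.0 ± 7.94 RPKM, Tbc1d10c from 4.43 ± 0.504 to 8.81 ± 0.781 RPKM, and Plac8 from 55.1 ± 2.57 to 92.3 ± 10.5 RPKM. Angptl7, already higher with the transgene, rose further to 41.3 ± 9.14 RPKM (log2 fold change 1.36, SE 0.24, adjusted p = 0.0477). Clec11a, a growth factor of the C-type lectin family, rose from 19.4 ± 2.59 to 36.7 ± 7.14 RPKM, and Trabd2b from 5.01 ± 0.599 to 9.32 ± 0.0601 RPKM. Lmbrd2, Zbed6, Klhl11 and Mib1 passed whichever library was left out, Ccl5 lost its call without vehicle library 2 or pirfenidone library 1 (adjusted p = 0.060 for each), and Gprin3 without pirfenidone library 1 (0.055).

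In the mean, matrix genes stood higher with pirfenidone than with vehicle, but 0 collagens passed limma's threshold over all genes. Col1a1 had 361 ± 84.3 RPKM with pirfenidone and 187 ± 44.6 RPKM with vehicle (log2 fold change 0.95, SE 0.21, adjusted p = 0.0767). Col3a1 had 966 ± 280 and 478 ± 94.4 RPKM (0.99, SE 0.23, adjusted p = 0.0855). Fn1 had 454 ± 142 and 274 ± 54.1 RPKM (adjusted p = 0.158), and Acta2 55.5 ± 12.8 and 29.4 ± 3.20 RPKM (adjusted p = 0.0747). Wt1 had 15.3 ± 6.05 and 7.24 ± 1.37 RPKM (adjusted p = 0.162), and Tgfa 5.65 ± 0.0425 and 6.85 ± 0.825 RPKM (adjusted p = 0.252). All 18 collagens had fitted values above 0, with a median of 0.59, and 9 rose when adjusted over the list alone (camera adjusted p = 5.06e-07, adjusted p = 0.562 with an estimated correlation). Of 34 matrix glycoproteins 0 passed over all genes, and 5 rose when adjusted over the list alone (median 0.52, camera adjusted p = 1.24e-05, adjusted p = 0.562 with an estimated correlation). Mfap2, a microfibril protein, stood at 36.7 ± 5.11 and 20.8 ± 2.74 RPKM (adjusted p = 0.055). The cross-linking and protease list had a median of 0.35 with 0 of 34 passed and 1 that fell, P4ha2, when adjusted over the list alone (camera adjusted p = 0.00527, adjusted p = 0.611 with an estimated correlation). Contractile genes had 0 of 20 passed and 8 that rose when adjusted over the list alone (median 0.45, camera adjusted p = 4.24e-05, adjusted p = 0.562 with an estimated correlation). Smooth muscle and pericyte markers had 0 of 19 passed and 3 that rose when adjusted over the list alone (camera adjusted p = 0.00932, adjusted p = 0.611 with an estimated correlation). Fibroblast markers had 0 of 25 passed and 6 that rose when adjusted over the list alone (camera adjusted p = 0.00128, adjusted p = 0.611 with an estimated correlation). Fibroblast regulators had 0 of 30 passed, also when adjusted over the list alone (camera adjusted p = 0.00222, adjusted p = 0.562 with an estimated correlation). The TGF-beta list was not called (camera adjusted p = 0.156), with 2 that rose when adjusted over the list alone, and Tgfb2 stood at 17.1 ± 3.84 and 8.68 ± 0.388 RPKM (adjusted p = 0.0731). Of fat transcripts, Adipoq (adiponectin) stood at 27.6, 30.3 and 4.37 RPKM in pirfenidone libraries 1, 2 and 3 and at 10.6, 1.19 and 0.43 RPKM in vehicle libraries. Adipose markers had a median of 1.78 with 0 of 9 passed, also when adjusted over the list alone (camera adjusted p = 0.00243, adjusted p = 0.611 with an estimated correlation). Acta1 stood at 128, 574 and 0.946 RPKM with pirfenidone, and the skeletal muscle list was not called (camera adjusted p = 0.996), with a median of 0.16 and a camera direction of lower. Cardiac markers had 0 of 15 passed and 9 that rose when adjusted over the list alone (median 1.28, camera adjusted p = 6.73e-06, adjusted p = 0.562 with an estimated correlation). The cross-linking list was not called without pirfenidone library 1 (adjusted p = 0.064), nor the smooth muscle list without vehicle library 2 (0.059) or pirfenidone library 1 (0.071). Without pirfenidone library 3, Col1a1 (limma adjusted p = 0.009), Col3a1 (0.006), Fn1 (0.014), Acta2 (0.006) and Wt1 (0.015) all passed as higher. None of these genes passed when any other single library of this comparison was left out. Library 3 lay apart from its companions on the second component, towards the vehicle libraries, so leaving it out favours such calls by itself. The pirfenidone libraries kept, 1 and 2, were also those with the most Adipoq and Acta1.

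T cell, B cell and natural killer cell markers, which were lower with the transgene, had higher fitted values with pirfenidone, and alveolar type 2 markers had mostly lower ones. Neutrophil markers, also lower with the transgene, had a median of -0.06 with pirfenidone, with 5 of 11 members above 0 and 0 passed by limma (camera adjusted p = 0.982). All 19 T cell markers had fitted values above 0, with 0 passed over all genes and 10 that rose when adjusted over the list alone (median 0.52, camera adjusted p = 1.33e-06, adjusted p = 0.562 with an estimated correlation). Tcf7 stood at 17.5 ± 1.48 RPKM with pirfenidone and 11.2 ± 1.22 RPKM with vehicle (adjusted p = 0.0588). Of 15 B cell markers 0 passed, and 6 rose when adjusted over the list alone (camera adjusted p = 1.73e-05, adjusted p = 0.562 with an estimated correlation). Cxcr5 stood at 3.66 ± 0.340 and 2.11 ± 0.453 RPKM (adjusted p = 0.070). Natural killer cell markers had 0 of 11 passed and 1, Nkg7, that rose when adjusted over the list alone (camera adjusted p = 0.00145, adjusted p = 0.562 with an estimated correlation). Interstitial macrophage and monocyte markers had 1 of 25 that rose, Plac8, with 2 when adjusted over the list alone (camera adjusted p = 0.0012, adjusted p = 0.611 with an estimated correlation). Fcrls stood at 15.9 ± 6.49 and 5.97 ± 1.23 RPKM (adjusted p = 0.0867). Mast cell, basophil and eosinophil markers (median 0.53, camera adjusted p = 0.0293, adjusted p = 0.562 with an estimated correlation), plasma cell markers (median 0.51, camera adjusted p = 0.0325, adjusted p = 0.611 with an estimated correlation) and interferon-induced genes (median 0.30, camera adjusted p = 0.011, adjusted p = 0.611 with an estimated correlation) had 0 members passed, also when adjusted over the list alone. Lymphatic markers had 0 of 7 passed and 2 that rose when adjusted over the list alone (camera adjusted p = 0.00243, adjusted p = 0.562 with an estimated correlation). Immediate early genes had 0 of 20 passed and 1, Myc, that rose when adjusted over the list alone (camera adjusted p = 0.0293, adjusted p = 0.611 with an estimated correlation). Among the lists with lower values, alveolar type 2 markers had 0 of 15 passed and 6 that fell when adjusted over the list alone (median -0.54, camera adjusted p = 2.74e-06, adjusted p = 0.562 with an estimated correlation). Napsa stood at 199 ± 53.4 RPKM with pirfenidone and 294 ± 21.7 RPKM with vehicle (adjusted p = 0.113), and Hc (complement C5) at 52.3 ± 13.9 and 99.0 ± 8.72 RPKM (adjusted p = 0.055). Acaca, the acetyl-CoA carboxylase of fatty acid synthesis, fell from 18.8 ± 1.05 to 12.7 ± 1.03 RPKM (log2 fold change -0.53, SE 0.08, adjusted p = 0.0371), beside 11.5 ± 0.326 RPKM in control lungs. It was the 1 gene of 25 that fell in the list of lipid and surfactant synthesis, with 4 when adjusted over the list alone (camera adjusted p = 0.0012, adjusted p = 0.562 with an estimated correlation). Alveolar type 1 markers had a median of -0.37 with 0 of 15 passed and 1, Pdpn, that rose when adjusted over the list alone (camera adjusted p = 0.00624, adjusted p = 0.611 with an estimated correlation). Club cell markers had 0 of 14 passed and 1, Hp, that fell when adjusted over the list alone (camera adjusted p = 0.015, adjusted p = 0.562 with an estimated correlation). Basal and goblet markers (median -0.36, camera adjusted p = 0.00615, adjusted p = 0.611 with an estimated correlation), cell cycle genes (median -0.26, camera adjusted p = 0.00222, adjusted p = 0.727 with an estimated correlation) and ribosomal protein genes (median -0.24, camera adjusted p = 4.85e-07, adjusted p = 0.611 with an estimated correlation) had 0 members passed, also when adjusted over the list alone. Endothelial markers were not called (camera adjusted p = 0.268), nor were EGF receptor ligands and ERK feedback genes (camera adjusted p = 0.686, median -0.01 and mean 0.02). Erbb3 of the latter stood at 9.51 ± 4.95 and 21.9 ± 2.35 RPKM (adjusted p = 0.0764). Called lists that lost the call without 1 library were immediate early genes (vehicle 1, adjusted p = 0.105, vehicle 3, 0.057, pirfenidone 3, 0.254) and interferon-induced genes (vehicle 2, 0.156, vehicle 3, 0.059, pirfenidone 2, 0.091). So did plasma cell markers (vehicle 1, adjusted p = 0.119, vehicle 2, 0.05005, pirfenidone 1, 0.110, pirfenidone 2, 0.095) and cell cycle genes (vehicle 2, 0.081, vehicle 3, 0.052). The others were mast cell markers (vehicle 2 and 3, adjusted p = 0.059 for each), club cell markers (vehicle 1, 0.104) and lipid synthesis (vehicle 1, 0.061).

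In all, 97 of 13849 genes changed between TGFα mice on pirfenidone and on vehicle, 21 higher and 76 lower, and 2862 had an unadjusted p under 0.05. Replicates did not overlap for 24.4% of genes, against 10% by chance. Camera called 25 of 44 lists, 18 higher and 7 lower, and 0 with an estimated correlation. Mixed splits of the same libraries gave 10 to 27 called lists. Of these 97 genes, 2 stood in called lists, Plac8 and Acaca, so the called lists rest mainly on members that did not pass singly. The 76 lower genes had a median transcript length of 8180 nt and a GC content of 41.5%, beside 3351 nt and 49.9% over all tested genes. The count was 28 without vehicle library 1, 12 without vehicle library 2, 16 without vehicle library 3, 10 without pirfenidone library 1, 19 without pirfenidone library 2 and 2124 (1060 higher, 1064 lower) without pirfenidone library 3. It was 29 after a correction for GC content and transcript length, 28 of them among the 97. Lst1, Clec11a, Tbc1d10c, Trabd2b, Atp6v0a4, Xiap, Acaca and Plac8 lost their calls without any 1 of the 3 vehicle libraries or of pirfenidone libraries 1 and 2, and Angptl7 without each of these but vehicle library 1 (adjusted p from 0.0929 to 0.217).

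The design also asks whether genes changed between TGFα vehicle and control lungs, by the transgene or Dox, moved back towards control with pirfenidone. Of the 3222 genes changed between TGFα vehicle and control lungs, 2453 (76.1%) had a fold change of opposite sign with pirfenidone, 70.5% of the 1665 higher genes and 82.2% of the 1557 lower genes. Both comparisons share the TGFα vehicle libraries, and simulated data without a drug effect gave a mean of 58.0% (SD 16.8), with a share as high in 19 of 100 data sets. The median gene returned 27.2% of its transgene change, and the same simulated data gave a mean of 5.71% (SD 11.99), with a value as high in 5 of 100 data sets. Of 82 genes that passed in both comparisons, 77 moved in opposite directions, such as Lmbrd2 and Ccl5. As many as 77 such genes were found in 3 of the 100 simulated data sets. The simulated data took the observed difference between TGFα vehicle and control, with its noise, as the true one. Opposite moves by chance may therefore be understated there, and these numbers of data sets may be too low. The other 5, Angptl7, Trabd2b, Plekha4, Car11 and Hpca, moved the same way, and the last 3 were chosen after their values were seen.

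TGFα mice on pirfenidone were also compared with control mice, to ask what still differed from control lungs under the drug. Matrix transcripts stood far above control. Col1a1 rose 4.10-fold, from 88.1 ± 4.89 to 361 ± 84.3 RPKM (n = 3, log2 fold change 2.00, SE 0.21, adjusted p = 0.00114). Col3a1 rose 3.95-fold, from 245 ± 23.4 to 966 ± 280 RPKM. Fn1 rose 6.67-fold, from 68.0 ± 7.24 to 454 ± 142 RPKM (log2 fold change 2.67, SE 0.24, adjusted p = 0.000647). Lum rose 33.4-fold, from 6.67 ± 1.38 to 223 ± 103 RPKM, Ptn from 0.462 ± 0.0305 to 56.5 ± 18.7 RPKM, and Angptl7 from 0.262 ± 0.127 to 41.3 ± 9.14 RPKM. Wt1 rose 5.83-fold, from 2.63 ± 1.14 to 15.3 ± 6.05 RPKM (adjusted p = 0.00412). Acta2 stood at 55.5 ± 12.8 RPKM beside 78.7 ± 13.8 RPKM in control (log2 fold change -0.51, SE 0.19, adjusted p = 0.0922). Tgfa stood at 5.65 ± 0.0425 beside 6.84 ± 0.789 RPKM (adjusted p = 0.162). Among the decreases, Npr3, a natriuretic peptide receptor, fell 7.16-fold, from 22.6 ± 6.30 to 3.16 ± 0.814 RPKM (log2 fold change -2.49, SE 0.19, adjusted p = 0.000469). Bmp6 fell 4.39-fold and Msln (mesothelin) 4.05-fold, from 30.9 ± 6.64 to 7.64 ± 6.30 RPKM. Msln lost its call without control library 1 (adjusted p = 0.0698), control library 2 (0.0653) or pirfenidone library 1 (0.0592).

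Of 18 collagens, 11 rose and 0 fell, with 12 when adjusted over the list alone (camera adjusted p = 8.87e-07, adjusted p = 0.461 with an estimated correlation). Matrix glycoproteins had 22 of 34 members that rose and 1, Vtn, that fell, with 23 and 3 when adjusted over the list alone (camera adjusted p = 2.17e-07, adjusted p = 0.461 with an estimated correlation). The cross-linking and protease list had 14 of 34 that rose and 2, Mmp9 and Loxl4, that fell, with 15 and 2 when adjusted over the list alone (camera adjusted p = 0.000599, adjusted p = 0.509 with an estimated correlation). The TGF-beta list had 8 of 22 that rose, with 10 and 2 that fell when adjusted over the list alone (camera adjusted p = 0.00361, adjusted p = 0.461 with an estimated correlation). Contractile genes were not called (camera adjusted p = 0.862), with 1, Itgav, that rose and 2, Synm and Myh11, that fell among 20. Fat and muscle transcripts stood beside these: adipose markers had a median of 2.45 with 0 of 9 passed by limma and 7 that rose when adjusted over the list alone (camera adjusted p = 0.0199, adjusted p = 0.61 with an estimated correlation). Skeletal muscle markers had a median of 2.81 with 0 of 12 passed, also when adjusted over the list alone (camera adjusted p = 0.0249, adjusted p = 0.687 with an estimated correlation). Cardiac markers had 1 of 15 that fell, Myh6, and 0 when adjusted over the list alone (camera adjusted p = 0.0297, adjusted p = 0.659 with an estimated correlation, median -0.59, mean -0.03). Interstitial macrophage and monocyte markers had 9 of 25 that rose, among them C1qa, C1qb and C1qc of the complement system, with 12 when adjusted over the list alone (camera adjusted p = 0.000545, adjusted p = 0.545 with an estimated correlation). EGF receptor ligands and ERK feedback genes had 9 of 26 that rose and 2, Ccnd1 and Epha2, that fell, with 11 and 2 when adjusted over the list alone (camera adjusted p = 0.0157, adjusted p = 0.509 with an estimated correlation). Ribosomal protein genes had 32 of 48 that rose (14 after the correction for GC content and transcript length), with 47 when adjusted over the list alone (camera adjusted p = 2.59e-13, adjusted p = 0.509 with an estimated correlation). Respiratory chain subunits had 6 of 35 that rose (2 with median-of-ratios scaling, 3 with upper-quartile scaling and 2 after the correction), also when adjusted over the list alone (camera adjusted p = 7.78e-05, adjusted p = 0.557 with an estimated correlation). Lists that lost the call without 1 library were adipose markers (control 3, adjusted p = 0.062, pirfenidone 1, 0.1003, pirfenidone 2, 0.060), skeletal muscle markers (control 3, 0.063, pirfenidone 1, 0.055, pirfenidone 2, 0.212), cardiac markers (control 2, 0.153, pirfenidone 3, 0.068, and 0.084 with median-of-ratios scaling) and EGF receptor genes (control 3, 0.127).

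Endothelial markers had 20 of 25 members that fell against control, with 22 when adjusted over the list alone (camera adjusted p = 2.59e-13, adjusted p = 0.461 with an estimated correlation). Eng stood at 46.1 ± 1.54 RPKM. Ciliated cell markers had 16 of 19 that fell, with 18 when adjusted over the list alone (camera adjusted p = 6.38e-10, adjusted p = 0.461 with an estimated correlation). Alveolar type 1 markers had 12 of 15 that fell, with 13 when adjusted over the list alone (camera adjusted p = 4.42e-09, adjusted p = 0.461 with an estimated correlation). Club cell markers had 4 of 14 that fell, Hp, Gabrp, Scgb3a2 and Cyp2f2, with 5 when adjusted over the list alone (camera adjusted p = 0.000545, adjusted p = 0.461 with an estimated correlation). Basal and goblet markers had 3 of 10 that fell, Muc5b, Krt19 and Krt7, also when adjusted over the list alone (camera adjusted p = 0.00673, adjusted p = 0.523 with an estimated correlation). Neutrophil markers had 6 of 11 that fell and erythroid markers 5 of 6, among them Slc4a1, Alas2 and Bpgm, both also when adjusted over the list alone (camera adjusted p = 0.000157 and 0.000303, adjusted p = 0.461 for each with an estimated correlation). T cell markers had 3 of 19 that fell, among them Cd27 and Cd3e, also when adjusted over the list alone (camera adjusted p = 2.67e-05, adjusted p = 0.509 with an estimated correlation). B cell markers had 5 of 15 that fell, among them Pax5, Blk, Cxcr5 and Spib, also when adjusted over the list alone (camera adjusted p = 0.000157, adjusted p = 0.509 with an estimated correlation). Natural killer cell markers had 3 of 11 that fell, Klrd1, Prf1 and Gzma, with 5 when adjusted over the list alone (camera adjusted p = 0.000157, adjusted p = 0.461 with an estimated correlation). Platelet markers had 3 of 8 that fell (5 after the correction), Itgb3, Ppbp and Clec1b, with 5 that fell and 1 that rose when adjusted over the list alone (camera adjusted p = 0.00701, adjusted p = 0.509 with an estimated correlation). Immediate early genes had 5 of 20 that fell, Nr4a3, Klf4, Atf3, Fosb and Klf6, and 2, Egr1 and Egr3, that rose, with 8 and 2 when adjusted over the list alone (camera adjusted p = 0.00713, adjusted p = 0.509 with an estimated correlation). Xenobiotic and antioxidant genes had 5 of 30 that fell (8 after the correction), Cyp4b1, Fmo1, Gclc, Cyp2s1 and Cyp2f2, and 1, Cyp1b1, that rose, with 8 and 1 when adjusted over the list alone (camera adjusted p = 0.00367, adjusted p = 0.545 with an estimated correlation). The unfolded protein response list had 3 of 25 that fell (7 after the GC and length correction), the chaperones Hyou1 and Hspa5 and the asparagine synthetase Asns, and 0 when adjusted over the list alone by limma (camera adjusted p = 0.000788, adjusted p = 0.545 with an estimated correlation). Lipid and surfactant synthesis had 7 of 25 that fell and 1, Lpl, that rose, with 7 and 2 when adjusted over the list alone (camera adjusted p = 0.0285, adjusted p = 0.545 with an estimated correlation). The calls of platelet markers and the unfolded protein response (adjusted p = 0.055 for each) and of lipid synthesis (0.127) were lost without control library 3, and that of basal and goblet markers without pirfenidone library 1 (0.055).

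In all, 2545 of 13849 genes changed between pirfenidone-treated TGFα and control lungs, 1473 higher and 1072 lower, of which 385 and 190 changed at least 2-fold. The higher genes made up 57.9% of the changed genes, but 46.2% with median-of-ratios scaling, 49.1% with upper-quartile scaling and 43.7% after the correction for GC content and transcript length. Replicates did not overlap for 37.3% of genes, against 10% by chance. Camera called 26 of 44 lists, 10 higher and 16 lower, and 0 with an estimated correlation. Mixed splits of the same libraries gave 15 to 27 called lists. Among the 2545 genes, 795 were higher and 816 lower than control both with vehicle and with pirfenidone. If the calls were independent, 177 and 121 would overlap. Both comparisons share the control libraries, and in simulated data without any group difference the covariance of their fold changes across genes was 0.0285 (SD 0.0247), beside 0.198 observed. The count was 1161 without control library 1, 1145 without control library 2, 1287 without pirfenidone library 1 and 1121 without pirfenidone library 2.

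**Figure D3:**
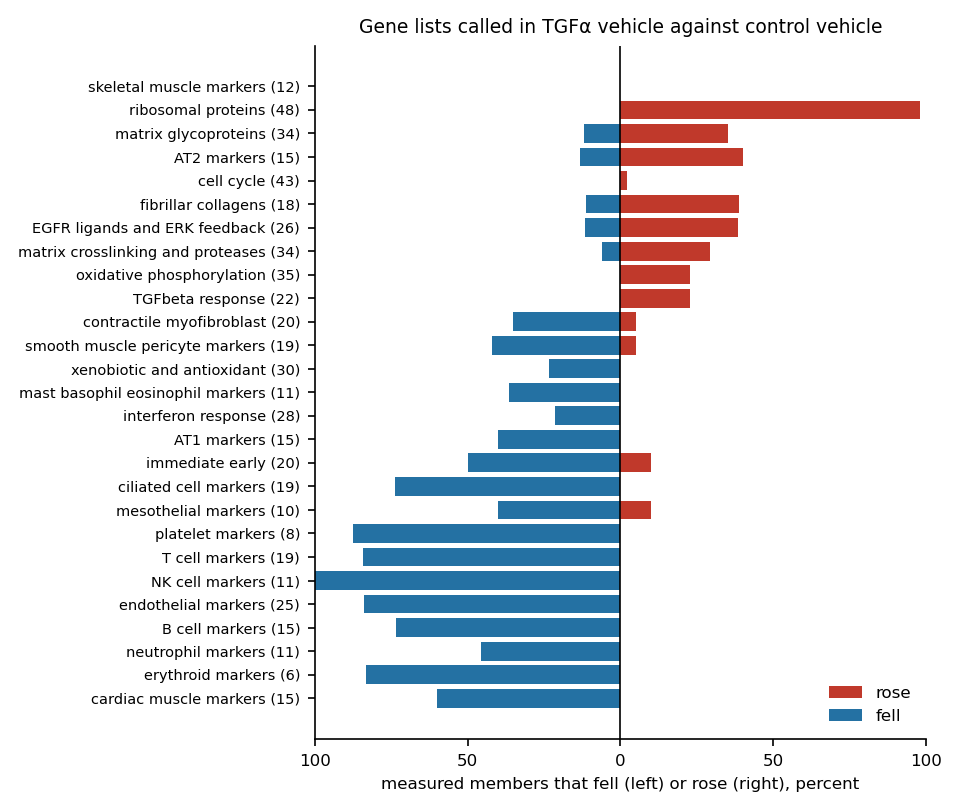
Percent of measured members (x axis) that fell (left) or rose (right) between TGFα vehicle and control lungs in each of the 27 lists called by camera (y axis, n = 3 mice per group). The ribosomal protein list had 47 of 48 members that rose, and the endothelial list 21 of 25 that fell.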

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

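The correction for GC content and transcript length, the fit without TGFα vehicle library 1 and pirfenidone library 3, and the sample weights were chosen after the data were seen. Against 3222 genes for TGFα vehicle and control, 97 for pirfenidone and vehicle, and 2545 for pirfenidone and control, a 1.5-fold minimum gave 1862, 64 and 1532 genes and an adjusted p threshold of 0.01 gave 1085, 22 and 782, both fewer by construction. Leaving out 1 library gave 1317 to 3769, 10 to 2124 and 1121 to 3069 genes. Leaving out both libraries gave 4960 and 3032 genes in the first and second comparison (3602 in the third), and held all 97 genes called with every library. Both libraries were picked for standing nearer to the other group, which favours more calls between pirfenidone and vehicle. Sample weights fitted gene by gene gave 8034, 5274 and 5921 genes. The default weight estimate did not converge and gave 9244, 6463 and 6451, counts seen before the other method was chosen. For pirfenidone and vehicle, the count was also 63 without a filter (more genes tested), 11 with only those 2 groups in the fit (fewer libraries), 21 with a replicate block and 29 after the GC and length correction. The cause was not tested for the leave-outs, the weights, the block or the correction. The block was tried once because groups share replicate numbers. Libraries of the same number in different groups had residuals correlated across genes from -0.136 to 0.458. Of 9 libraries, 5 correlated best, among libraries of other groups, with a library of their own number. The labels do not say what the numbers mark, so pairs are neither shown nor excluded. Other scalings, a filter of at least 1 CPM in at least 3 libraries (14845 genes tested), limma-voom and a pseudocount of 0.1 gave counts within 1.5 times the first values in all 3 comparisons. DESeq2's Wald test, planned for raw counts, was not run, since the deposited values are RPKM.

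Camera called 27, 25 and 26 of 44 lists with the preset correlation. With an estimated correlation it called 0, 0 and 0, with 3, 2 and 2 lists at an unadjusted p under 0.05. The test fry called 20, 0 and 16 lists, with 23, 13 and 22 at an unadjusted p under 0.05. Leaving out 1 library gave 25 to 32, 20 to 27 and 24 to 30 lists. Besides the single libraries, other settings ended some list calls. Between TGFα vehicle and control, mast cell markers lost the call with median-of-ratios scaling (adjusted p = 0.051), collagens with the block (0.073), and the TGF-beta and skeletal muscle lists without both libraries (0.058 and 0.231). Between pirfenidone and vehicle, basal and goblet markers lost it without a filter (0.053), plasma cell markers with the block (0.053), and immediate early genes, lipid synthesis and club cell markers without both libraries (0.502, 0.075 and 0.066). Between pirfenidone and control, cardiac markers lost it with median-of-ratios scaling, no filter, the block, the GC and length correction and both libraries left out (0.068 to 0.093), basal and goblet markers without a filter (0.131), lipid synthesis after the correction (0.095) and EGF receptor genes without both libraries (0.060). Of genes named for pirfenidone and vehicle, the correction ended the calls of Angptl7, Clec11a, Tbc1d10c, Xiap and Acaca (adjusted p from 0.0877 to 0.127) and limma-voom those of Lst1, Tbc1d10c and Xiap (0.0513 to 0.0673). The replicate block ended the calls of Angptl7, Lst1, Clec11a, Tbc1d10c, Trabd2b, Atp6v0a4, Xiap, Acaca and Plac8 (0.0786 to 0.101). The 2-group fit ended those of the same 9 genes and of Ccl5 and Gprin3 (0.0530 to 0.102). No called list's median changed sign under the 3 scalings, and of the named genes only Tgfa did, in TGFα vehicle against control. The share of transgene-changed genes that moved the opposite way with pirfenidone, 76.1%, was 81.4% without both libraries and 72.4% to 85.4% on leaving out 1 library. No named gene or list reversed. Besides the values given beside the results, list counts in the text that moved by over 1.5 times with another scaling or the correction moved by 1 gene. On leaving out 1 library, fold changes of named genes kept their side of the threshold 427 times, lost the call 34 times and gained it 1 time for TGFα vehicle and control. For pirfenidone and vehicle these numbers were 351, 47 and 52, and for pirfenidone and control 69, 3 and 0. Depth limits the low genes: 3 reads equalled 0.159 to 0.263 RPM.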

Other observations

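The list of 18 clock genes was called in none of the 3 comparisons, with members that went both ways. Between TGFα vehicle and control lungs, 5 rose, Nr1d2, Dbp, Per3, Hlf and Tef, and 3 fell, Npas2, Ciart and Arntl, with 6 and 4 when adjusted over the list alone (camera adjusted p = 0.323). Dbp, an output gene of the clock chosen after its values were seen, stood at 3.62, 4.12 and 3.20 RPKM in control libraries, 27.6, 21.1 and 16.7 RPKM with vehicle, and 55.3, 50.04 and 33.5 RPKM with pirfenidone. Arntl, which encodes the clock activator BMAL1 and was chosen the same way, had a log2 fold change of -0.61 with vehicle and -1.50 with pirfenidone, both against control. The labels give no time of collection. Between pirfenidone and vehicle 0 clock genes passed limma's threshold over all genes (2 fell with median-of-ratios scaling and 2 with upper-quartile scaling), and 6 rose and 4 fell when adjusted over the list alone (camera adjusted p = 0.113). Between pirfenidone and control 6 rose, Dbp, Nr1d2, Per3, Hlf, Tef and Per2, and 4 fell, Npas2, Arntl, Nfil3 and Clock, with 8 and 4 when adjusted over the list alone (camera adjusted p = 0.113).

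Glycolysis and hypoxia genes had 6 of 23 that rose with the transgene and 3 that fell, Pfkfb3, Vegfa and Pfkp, with 10 and 3 when adjusted over the list alone (camera adjusted p = 0.0856). Ankrd37, a hypoxia-induced gene, rose from 2.93 ± 0.564 to 36.0 ± 15.6 RPKM (n = 3, limma adjusted p = 0.00144). Among apoptosis and cell cycle arrest regulators 3 of 28 rose, the cell cycle inhibitors Cdkn2a and Cdkn2b and Trp53, and 8 fell, with 4 and 9 when adjusted over the list alone, and Tnfsf10, a death ligand, fell from 43.6 ± 4.68 to 20.3 ± 1.17 RPKM. Lipid and surfactant synthesis genes had 6 of 25 that rose with the transgene, Acaca, Acly, Fasn, Srebf1, Lpcat1 and Lpl, and 3 that fell (5 with median-of-ratios scaling), Elovl1, Cd36 and Hmgcs1, and the list was not called (median -0.08, mean 0.06, camera adjusted p = 0.834). Dendritic cell markers had 4 of 19 that fell, Cd209a, Siglech, Ccr7 and Flt3, and 1, Ciita, that rose, and the list was not called. Of 17 alveolar macrophage markers 1 fell, Car4, which the endothelial list also holds.

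The tests of the 3 patterns below and the splits behind the counts for TGFα vehicle and control and for pirfenidone and vehicle were chosen after those results were seen. The 76 genes lower with pirfenidone than with vehicle had long transcripts with low GC content. A smooth bias of the libraries with GC content and length as the whole cause predicts a median near 0 after the correction. The median log2 fold change was -0.68 before and -0.5809 after it, with a median SE of the single genes of 0.103 and 0.101. Of the 76 genes, 24 still passed. The genes were picked by this same comparison, which by itself keeps their median below 0. So the test cannot tell whether such a bias is the whole cause. A batch shared by the 3 vehicle libraries and a rise with the transgene that the drug returned cannot be told apart, because the same 3 libraries stand in both comparisons. Their median was 0.6978 for vehicle against control and -0.0862 for pirfenidone against control, as either explanation predicts.

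TGFα vehicle library 1 and pirfenidone library 3 stood between the groups on a scale of 588 genes. These genes passed with at least a 2-fold change between the other vehicle libraries (mean 0) and the other pirfenidone libraries (mean 1). Picking the genes by those libraries moves any left-out library towards the middle, so part of a middle position was set in advance. Over all tested genes, pirfenidone library 3 correlated at 0.9831 and 0.9881 with vehicle libraries 2 and 3, and at 0.9644 and 0.9567 with pirfenidone libraries 1 and 2. For vehicle library 1 these values were 0.9744 and 0.9693, and 0.9705 and 0.9682. Vehicle libraries 2 and 3 correlated at 0.9884 with each other, and pirfenidone libraries 1 and 2 at 0.9858. By this measure pirfenidone library 3 was almost as close to vehicle library 3 as vehicle library 2 was. Vehicle library 1 had a median position of 0.3528 (quartiles 0.189 and 0.548) and pirfenidone library 3 one of 0.2205 (quartiles 0.102 and 0.359). An exchange of these 2 libraries or a wrong group label of pirfenidone library 3 alone cannot be told apart from differences between mice, since 1 mouse decides each. On the scale of 588 genes, vehicle library 1 lies nearer to its own group. On the second principal component, at 3.73, it lies nearer to pirfenidone libraries 1 and 2 (28.3 and 33.6) than to vehicle libraries 2 and 3 (-26.9 and -27.1). The exchanged groups gave 1050 genes where the labelled ones gave 97. Different amounts of fat and muscle in the lung samples also stay open: adipose markers went with the position, with medians of 2.1477 (SE 0.365) for vehicle library 1 over 2 and 3 and 2.31 (SE 0.284) for pirfenidone libraries 1 and 2 over 3. A plain dilution by them predicts that lung lists fall together. In pirfenidone libraries 1 and 2 over 3, however, alveolar type 2 markers had a median of -0.60 (SE 0.171) and ciliated markers 0.21 (SE 0.0512). No label tells which part of the lung was taken. Each SE of a list median given here is over the genes of the list and holds no spread between mice.

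Endothelial, ciliated, T, B and natural killer cell and blood cell lists were lower in TGFα vehicle than in control lungs, though no list was called with an estimated correlation. Dilution by RNA of another cell type is argued against only if alveolar macrophages did not change in number. Alveolar macrophage markers had a median of 0.12 (SE 0.151) and endothelial markers -1.04 (SE 0.140), a difference of 1.164. These SEs are over the genes of a list and hold no spread between mice. A rise of the macrophages could give the same difference, so the test cannot exclude dilution. For 6 lists of blood cells the medians lay between -1.28 and -0.95, a range of 0.3216. Less blood in the TGFα lungs may explain these, but the endothelial median lies in the same range, so the range does not single out blood. Medians of interstitial macrophage and monocyte markers (0.32) and of mast cell, basophil and eosinophil markers (-0.38) lay outside it. Fewer resident cells stay open as a biological explanation and were not tested.

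The 6 libraries of each comparison have 10 splits into 3 against 3, the real one included, too few for a share under 0.05. Counting the real split, as many genes were changed in 1 split for TGFα vehicle and control (3222, highest other 0), 2 for pirfenidone and vehicle (97, highest other 1050) and 1 for pirfenidone and control (2545, highest other 31). The split with 1050 genes set vehicle library 1 with pirfenidone libraries 1 and 2, the groups that an exchange of 2 libraries would give, and points to a structure of the samples. Counted the same way, as many lists were called in 2 splits (27, highest other 27), 3 splits (25, highest other 27) and 3 splits (26, highest other 27). The other splits called 17 to 27, 10 to 27 and 15 to 27 lists. The number of lists called by camera at the preset correlation therefore does not set the labelled groups apart from mixed ones. The 6 TGFα libraries have 20 splits, the real one included, also too few, and 6 of them gave an opposite share of 76.1% or more (highest other 89.2%).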
